A study of Mus musculus with 16 samples.

How the data were processed

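RNA was measured by sequencing in 16 libraries from the striatum of 9-week-old male C57BL/6J mice. Astrocytes of these mice expressed bARK, a peptide of the β-adrenergic receptor kinase that attenuates Gq signalling, or bARK(D110A), a version with a substitution in the part of the kinase that binds Gq. Each mouse gave RNA from cleared striatal lysate (input) and RNA precipitated with ribosomes through a hemagglutinin tag in astrocytes (IP), per the labels' protocols. The 4 groups, bARK(D110A) input, bARK(D110A) IP, bARK input and bARK IP, held 4 libraries each. The labels number the libraries of a construct 1 to 4, and the same number in input and IP was read as the same mouse. They do not say in words that each number is another mouse, so p-values measure the spread between these samples.

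The labels' protocols describe removal of DNA and purification of RNA with a micro-scale column kit, then paired-end libraries made with a Nugen Ovation kit and mRNA enrichment from 100 ng of RNA. Base calls were converted with bcl2fastq 2.17, and STAR, HTSeq, limma and mouse build mm10 are named, all per the submitters' processing notes. The versions of STAR and HTSeq, the annotation and the strand setting of the counting were not given in the sources used here, so counts of overlapping or antisense genes are uncertain. So are those of ribosomal protein genes, which have many processed pseudogenes. The deposited table holds the count of reads per gene and library, as whole numbers, and the authors made it with the tools named above, per the submitters' processing notes. It has 24060 lines for 24058 gene symbols, of which 4017 had 0 reads in every library. The 2 symbols that stand on more than 1 line were left out of every gene named here. Of the symbols, 22600 matched a current symbol in the RefSeq gene table of GRCm38.p6, which is the same assembly as mm10, 1303 matched an older symbol only and 155 matched none. Gene coordinates come from that table and are 1-based.

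CPM values, the counts of a library scaled to a common total, were computed with effective library sizes from the trimmed mean of M values (TMM). Differential tests were run with edgeR 4.0.16 in R 4.3.3, as quasi-likelihood F tests with robust dispersion, TMM factors and the filterByExpr filter at its minimum count of 10, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Unless another test is named, every adjusted p for a gene is from this edgeR test. Where ± follows a log2 fold change of a gene, it gives the standard error from that test, with 4 libraries per group and no mouse block. IP was set against input in bARK(D110A) and in bARK, and the difference of the IP enrichment between constructs was tested as an interaction, in a fit of all 16 libraries. bARK was set against bARK(D110A) in the 8 IP libraries and, separately, in the 8 input libraries.

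The groups, tests, gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The 25 lists cover astrocytes, neurons in general, medium spiny neurons, interneurons, oligodendrocytes and their precursors, microglia, endothelial, mural, ependymal and red blood cells. They also cover 3 kinds of reactive astrocyte genes (pan-reactive, neurotoxic-type A1 and protective-type A2), Gq-coupled receptors, the Gq, phospholipase C and calcium store pathway, immediate early genes and interferon-stimulated genes. The rest are cholesterol synthesis, astrocyte transport, synapse-regulating astrocyte genes, nuclear-retained long noncoding RNAs, ribosomal protein genes without Rpl22, mitochondrially encoded genes and nuclear oxidative phosphorylation subunits. No mitochondrially encoded gene was in the table, so that list was not analysed here. Of the red blood cell genes, Alas2 alone passed the count filter. The other 23 lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, with a threshold of 0.05. Beside it stand camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance and compares them with no other genes. The lists overlap: 10 of the 14 transport genes are also astrocyte markers, and Cxcl10 is in the pan-reactive and the interferon list. The list call of a comparison is the camera result with the preset correlation.

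Genes were named by this rule. Rpl22, the ribosomal protein that carries the tag in common designs of this kind, and Grk2, listed under its older symbol Adrbk1, were named in every comparison. For IP against input, the rule took the 10 genes with the largest positive and the 10 with the largest negative log2 fold change that passed in both constructs, had no overlap in CPM between the 4 IP and 4 input libraries in either construct and had a mean of at least 10 CPM. They were ranked by the smaller of the 2 fold changes, and 3782 genes met these conditions on the higher side and 2647 on the lower side. For the construct comparisons and the difference of enrichment, it took up to 10 passing genes in each direction, and, where fewer than 10 passed, the genes with the smallest p up to 10, said not to pass. From each list it took 2 to 4 tested members with the smallest p in the comparison described, and in the construct comparisons every member past 0.05 over all genes, up to 10. Some genes that the rule picks are not described here. Genes named outside this rule are said to have been chosen after their values were seen.

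The total count was 29.1 to 37.3 M per input library of bARK(D110A), 27.8 to 38.0 M per input library of bARK, 44.6 to 51.4 M per IP library of bARK(D110A) and 41.5 to 47.2 M per IP library of bARK. Between 17457 and 18138 genes had at least 1 read in a library. At this depth and spread the median width of the 95% interval to each side of a log2 fold change was 0.172 for bARK against bARK(D110A) in IP, 0.176 in input and 0.255 for the difference of enrichment. The biological coefficient of variation was 0.126, 0.104 and 0.115 in these 3 fits. Each test was tested on simulated data in 4 draws, each with 200 changed genes of mixed fold sizes (200 per fold size over the draws). Genes were drawn independently and without mouse effects. Changed genes loosen the adjusted threshold for each other, so the shares below do not carry over to comparisons with few changed genes. Nor do they carry over to enrichment as observed, where far more genes were called. With 1.5-fold changes the share recovered was 66.5% in IP (14912 genes), 63.0% in input (15262 genes), 49.0% for the difference of enrichment (15672 genes), 66.0% for enrichment in bARK(D110A) (15669 genes) and 69.5% in bARK (15672 genes). With 2-fold changes it was 79.5%, 80.5%, 68.5%, 82.5% and 83.0% in the same order. With 1.25-fold changes it was only 22%, 31.5%, 6%, 28.5% and 28%, so most changes of that size were missed. False calls made up 5.95%, 7.76%, 4.06%, 4.53% and 3.34% of the calls.

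Within a group, each pair of libraries differed by more than sampling noise, with a chi-square per gene of 6.75 to 83.6, and no 2 libraries were identical. Input and IP libraries with the same number deviated together from their group means: the correlation of their deviations was 0.235 to 0.561 in bARK(D110A) and 0.164 to 0.314 in bARK, over 0.1 in 4 of 4 pairs each, and each of these 16 libraries correlated best with its own partner. The pairing comes from the labels' numbers and the protocol, which takes both RNAs from the same striata. A fit with mouse as a block was therefore run beside the reported fit for enrichment and for the difference of enrichment. Across constructs the same number marks different mice, and that check is given with the alternatives.

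The alternatives were DESeq2 size factors and library size alone in place of TMM, no count filter, a filter at 1 CPM in at least 4 libraries, the DESeq2 1.42.0 Wald test, limma-voom, the replicate block, other sets of libraries in the fit, an added fold limit of 2, and leaving out each library in turn. Leaving out both libraries of a mouse, and the block together with an estimated correlation, were chosen after seeing the data. Against TMM, library size alone shifted the median log2 fold change of IP against input by -0.16 in bARK(D110A) and -0.14 in bARK, so changes are given relative to TMM.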

Results

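The data describe RNA from the mouse striatum, taken as bulk lysate (input) and as RNA bound to tagged ribosomes of astrocytes (IP), with the Gq-attenuating peptide bARK or with its D110A counterpart expressed in astrocytes. Each of the 4 groups had 4 libraries. The total count averaged 32.2 ± 3.87 M reads (SD, n = 4) in bARK(D110A) input, 48.4 ± 2.91 M reads in bARK(D110A) IP, 33.4 ± 4.53 M reads in bARK input and 45.2 ± 2.54 M reads in bARK IP. The most abundant RNA was Malat1, a nuclear noncoding RNA, in each input library, with 0.671% to 0.970% of the counts, and Slc1a2, the main glutamate transporter of astrocytes, in each IP library, with 1.77% to 2.48%. These genes were chosen for their abundance after their values were seen. The 10 most abundant genes took 3.70% and 3.79% of the counts in the inputs and 5.89% and 6.43% in the IPs of bARK(D110A) and bARK. The first principal component held 80.6% of the variance and parted IP from input, and the second held 4.54%.

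The first question was which RNAs the precipitation enriched, and from which cells. In both constructs, astrocyte RNAs were higher in IP than in input and RNAs of microglia and endothelial cells were far lower. Pan-neuronal and oligodendrocyte RNAs stayed near their input level, so the IPs held RNA of these cells too. The mean log2 CPM of pan-neuronal markers spanned 7.13 to 7.79 in bARK(D110A) input and 7.31 to 7.82 in its IP. With bARK it spanned 7.38 to 7.52 and 7.25 to 7.63. Oligodendrocyte markers spanned 7.24 to 7.98 and 6.85 to 8.36 with bARK(D110A), and 7.30 to 7.45 and 7.22 to 7.91 with bARK. Aldh1l1, a folate enzyme used as an astrocyte marker, went from 69.4 ± 3.38 CPM (SD, n = 4) in input to 406 ± 19.1 CPM in IP with bARK(D110A), and from 69.2 ± 1.92 to 469 ± 29.9 CPM with bARK. C1qa, a complement subunit made by microglia, went from 106 ± 30.3 to 1.76 ± 0.39 CPM and from 94.4 ± 13.3 to 1.88 ± 0.47 CPM. Rpl22, the gene of a large-subunit ribosomal protein (chromosome 4, 152324436 to 152334082), rose in IP by 1.71 ± 0.11 (log2) with bARK(D110A) and 1.98 ± 0.11 with bARK. Its level was 91.6 ± 3.92 CPM in bARK(D110A) input, 303 ± 30.4 CPM in bARK(D110A) IP, 90.6 ± 10.5 CPM in bARK input and 358 ± 49.5 CPM in bARK IP. Reads of a tagged copy and of the mouse gene were not told apart here. Adrbk1 (now Grk2, chromosome 19, 4285999 to 4306222), from which the peptide derives, was at 93.2 ± 9.08 CPM in input and 102.6 ± 7.51 CPM in IP with bARK(D110A), a log2 fold change of 0.12 ± 0.09 (adjusted p = 0.257). With bARK it was at 90.6 ± 7.30 and 113.7 ± 15.8 CPM and rose by 0.32 ± 0.09 (adjusted p = 0.00416). With library size as the only scaling it did not pass (0.18, adjusted p = 0.0827), and the value with bARK(D110A) was then -0.04. Reads of the expressed peptide and of the mouse gene Adrbk1 were not told apart either, here or in the later comparisons.

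Of 15850 genes tested, 5786 were higher and 5891 lower in IP than in input with bARK(D110A), and 5966 and 6044 with bARK (edgeR, adjusted p under 0.05). With library size as the only scaling, the counts were 4459 and 7472 with bARK(D110A) and 4806 and 7331 with bARK. Both constructs shared 5448 higher and 5498 lower genes, where independent lists would share 2177.9 and 2246.4, and 1 gene passed in opposite directions. The log2 fold changes of the constructs correlated across genes, which are not independent replicates, with Pearson's r of 0.971 and Spearman's rho of 0.976.

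The genes with the largest enrichment in both constructs were led by Chrdl1, a secreted BMP antagonist of astrocytes that acts on synapses (chromosome X, 143285674 to 143394263; 2.75 ± 0.13 with bARK(D110A) and 2.96 ± 0.13 with bARK). Gfap, the intermediate filament of astrocytes (chromosome 11, 102887336 to 102897200), rose by 2.65 ± 0.31 and 3.01 ± 0.32. Aldh1l1 (chromosome 6, 90550768 to 90599171) rose by 2.53 ± 0.06 and 2.76 ± 0.06, and the water channel gene Aqp4 (chromosome 18, 15389394 to 15410982) by 2.48 ± 0.10 and 2.72 ± 0.10. The others were Cox6b2, a cytochrome oxidase subunit, Dcxr, a xylulose reductase, Eda2r, a receptor of the TNF receptor family, Gldc, of the glycine cleavage system, Acsbg1, an acyl-CoA synthetase, and Aass, of lysine breakdown. Their log2 fold changes lay between 2.49 (Aass) and 2.64 (Cox6b2) with bARK(D110A) and between 2.65 (Gldc) and 2.93 (Dcxr) with bARK.

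The largest depletion was that of Rmrp, the RNA of a nuclear and mitochondrial endoribonuclease (chromosome 4, 43492785 to 43493059), which fell from 776 ± 225 to 8.39 ± 3.78 CPM and from 908 ± 61.5 to 11.9 ± 4.44 CPM. Its log2 fold changes were -6.55 ± 0.39 and -6.25 ± 0.38. Next came genes of microglia and other leukocytes: Ctss, a lysosomal protease (-6.10 and -5.90), the complement genes C1qa (chromosome 4, 136895916 to 136898844; -5.93 and -5.66), C1qb (-5.89 and -5.53) and C1qc (-5.94 and -5.62), Selplg, a selectin ligand (-5.53 and -5.27), the CSF1 receptor gene Csf1r (-5.36 and -5.17), the integrin gene Itgam (-5.11 and -5.15) and Tmem119 (-5.35 and -5.10). Igj, the joining chain of secreted immunoglobulins, now Jchain, fell too (-5.74 and -5.51), with input levels that spread from 14.9 to 125.9 CPM between the mice with bARK(D110A).

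All 28 astrocyte markers rose in both constructs, over all genes and adjusted over the list alone, with median log2 fold changes of 2.07 and 2.35 (camera adjusted p = 2.07e-40 and 2.60e-41; with an estimated correlation, adjusted p = 0.00547 and 0.00878). Among them were Slc1a3, a glutamate transporter (2.43 ± 0.06 and 2.61 ± 0.06), Acsbg1, and Fgfr3, a growth factor receptor (2.33 ± 0.07 and 2.62 ± 0.08). All 14 transport genes rose too, with medians of 2.06 and 2.31 (adjusted p = 2.32e-24 and 3.93e-24; with an estimated correlation, adjusted p = 0.00547 and 0.00878). Examples were Slc38a3, which exports glutamine (2.37 and 2.58), and Gja1, the gap junction protein connexin 43 (2.38 and 2.56). Of 11 synapse-regulating genes, 10 rose, with medians of 1.72 and 1.91 (adjusted p = 3.37e-08 and 1.71e-08; with an estimated correlation, adjusted p = 0.00547 and 0.00878). They included the glypicans Gpc5 (2.25 and 2.51) and Gpc6 (1.66 and 1.89) and the secreted Sparcl1 (2.21 and 2.35). The 16 cholesterol synthesis genes all rose, with medians of 1.252 and 1.44 (adjusted p = 1.87e-06 and 3.66e-07; adjusted p = 0.349 and 0.299 with an estimated correlation), such as Nsdhl (1.23 and 1.35), Sc5d (1.24 and 1.45) and Hmgcs1, an early enzyme of the pathway (1.29 and 1.49). The counts adjusted over the list alone were the same for these 4 lists. With mouse as a block and an estimated correlation, chosen after seeing the data, adjusted p = 0.0512 and 0.0673 for astrocyte markers and 0.0569 and 0.0722 for transport genes, so that neither was called. In the same test adjusted p = 0.0459 and 0.0538 for synapse-regulating genes and 0.232 and 0.197 for cholesterol synthesis genes.

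**Figure D1:**
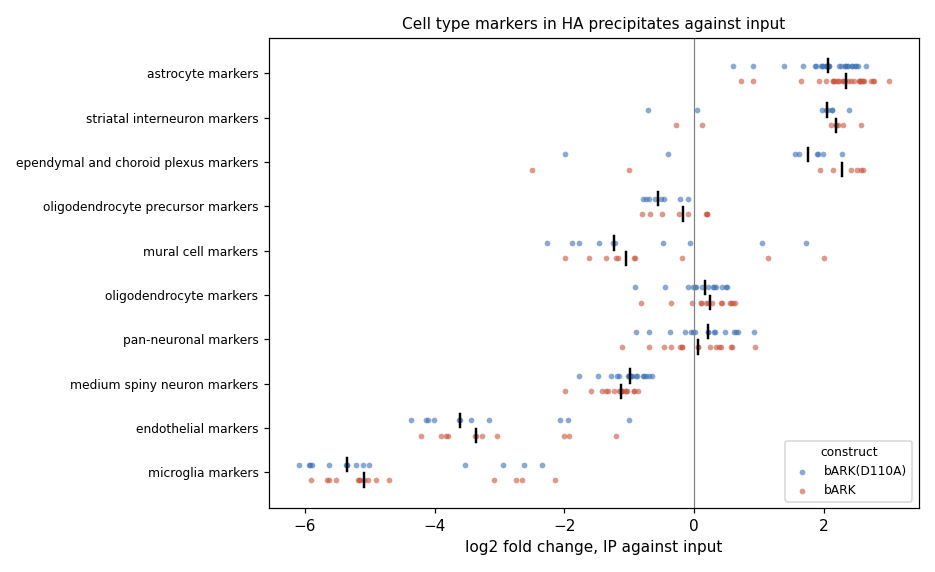
Log2 fold change of IP against input (x axis) for each member of 10 cell type lists (y axis), with bARK(D110A) in blue and bARK in red; each point is 1 gene and the black bar is the list's median. Astrocyte markers lie to the right of 0, with medians of 2.07 and 2.35, and microglia markers to the left, with medians of -5.35 and -5.10.

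Markers of other cells moved in several directions. All 15 microglia markers fell, with medians of -5.35 and -5.10 (adjusted p = 8.66e-29 and 9.48e-24; with an estimated correlation, adjusted p = 0.00547 and 0.00878), among them the fractalkine receptor gene Cx3cr1 (-5.22 ± 0.12 and -4.91 ± 0.11). All 11 endothelial markers fell, with medians of -3.61 and -3.37 (adjusted p = 1.36e-18 and 1.87e-15; with an estimated correlation, adjusted p = 0.00547 and 0.00878). The tight junction gene Cldn5 changed by -4.10 and -3.90, the transporter gene Slco1a4 by -3.63 and -3.37 and Ly6c1 by -4.37 and -4.21. All 18 markers of medium spiny neurons, the main striatal neurons, fell as well, with medians of -0.98 and -1.13 (adjusted p = 6.20e-08 and 2.57e-09; adjusted p = 0.277 and 0.211 with an estimated correlation). Arpp21 changed by -1.78 and -1.99, the adenosine receptor gene Adora2a by -1.48 and -1.59, and Ppp1r1b, the dopamine-regulated phosphatase inhibitor DARPP-32, by -0.99 and -1.13. By contrast, 6 of 8 interneuron markers rose and 0 fell, with medians of 2.05 and 2.19 (adjusted p = 9.11e-07 and 1.12e-06; adjusted p = 0.0585 and 0.0808 with an estimated correlation). The cholinergic enzyme gene Chat rose by 2.07 and 2.23, the neuropeptide genes Sst by 2.13 and 2.30 and Npy by 2.13 and 2.18, and the nitric oxide synthase gene Nos1 by 2.39 and 2.58. Counts adjusted over the list alone were the same in these 4 lists. With mouse as a block and an estimated correlation, adjusted p = 0.0173 and 0.0324 for microglia and for endothelial markers, which stayed called. Spiny neuron markers (adjusted p = 0.232 and 0.186) and interneuron markers (adjusted p = 0.146 and 0.183) were not called in that test. The red blood cell gene Alas2, an enzyme of heme synthesis, fell as well (-4.73 and -4.37).

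The remaining cell types were not called as lists. Of 16 pan-neuronal markers, 6 were higher and 3 lower with bARK(D110A), and 5 higher and 7 lower with bARK (medians 0.22 and 0.06; adjusted p = 0.987 and 0.643, camera's direction down for the latter). The splicing factor gene Rbfox3 fell (-0.89 and -1.11) and Tubb3, a neuronal tubulin, rose (0.48 and 0.39). With library size only as the scaling, the median of this list with bARK was -0.08. Of 14 oligodendrocyte markers, 0 were higher and 1 lower, and 1 higher and 1 lower (medians 0.17 and 0.24; adjusted p = 0.987, camera's direction down, and 0.882), and 0 passed adjusted over the list alone. Those that passed over all genes were Mobp, a myelin protein (-0.90, adjusted p = 0.012; -0.82, adjusted p = 0.0190), and, with bARK, Cnp (0.61, adjusted p = 0.01696). With bARK, Mobp did not pass without library 2 of IP (-0.72, adjusted p = 0.0562), nor Cnp without library 1 of IP (0.51, adjusted p = 0.0585). With bARK(D110A), Cnp (0.42, adjusted p = 0.0794) passed without library 3 of IP (0.60, adjusted p = 0.00506) or library 2 of input (0.57, adjusted p = 0.0335). Of 8 markers of oligodendrocyte precursors, 0 were higher and 6 lower with bARK(D110A), and 1 higher and 3 lower with bARK, 0 and 3 adjusted over the list alone (medians -0.56 and -0.16; adjusted p = 0.169 and 0.632), with Pcdh15 at -0.74 and -0.69. Of 10 mural markers 2 rose and 7 fell in each construct (medians -1.23 and -1.05; adjusted p = 0.116 and 0.293). Notch3 rose (1.73 and 2.00), and Vtn (-1.88 and -1.62) and Rgs5 (-1.77 and -1.35) fell. Of 8 ependymal and choroid plexus markers, 6 rose in each construct and 1 and 2 fell (medians 1.76 and 2.29; adjusted p = 0.618 and 0.628), with the ciliary regulator Foxj1 at 1.91 and 2.15. For the pan-neuronal, mural and ependymal lists the counts adjusted over the list alone were the same.

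Reactive astrocyte and interferon genes were tested as 4 lists, none of which the reported test called. Of 12 pan-reactive genes, 9 were higher and 1 lower with bARK(D110A) and 10 and 0 with bARK (medians 2.03 and 2.30), including the hyaluronan receptor gene Cd44 (1.96 and 2.28), the oncostatin M receptor gene Osmr (2.171 and 2.38) and Timp1, a protease inhibitor (2.33 and 3.34). Of 12 interferon-stimulated genes, 10 and 11 were higher (medians 1.55 and 1.80), such as Ifit3 (2.34 and 2.72) and Ifitm3 (1.71 and 2.02). Of 11 A1 genes 8 were higher and 3 lower in each construct (medians 1.57 and 1.78), with Ggta1 higher (1.76 and 2.03) and Srgn, a proteoglycan of blood cells, lower (-3.31 and -3.47). Of 11 A2 genes 5 were higher and 1 lower (medians 0.33 and 0.54; adjusted p = 0.897 and 0.778), with Cd109 higher (2.64 and 2.81) and Cd14, a receptor of myeloid cells, lower (-3.77 and -4.41). The counts adjusted over the list alone were the same. The reported test gave adjusted p = 0.116 and 0.0931 for the pan-reactive, 0.223 and 0.232 for the interferon and 0.846 and 0.778 for the A1 genes. With mouse as a block the pan-reactive list was called (adjusted p = 5.80e-05 and 1.55e-05), as were the A1 list (0.0285 and 0.0192) and the interferon list (3.07e-06 and 7.55e-07). With the block and an estimated correlation these adjusted p were 0.151 and 0.183, 0.411 and 0.399, and 0.273 and 0.243.

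Genes of the Gq pathway, which the peptide acts on, were found on both sides. Of 25 Gq-coupled receptors, 10 were higher and 6 lower with bARK(D110A) and 11 and 6 with bARK (medians 0.36 and 0.23; adjusted p = 0.223 and 0.369). The neurokinin receptor gene Tacr1 (2.20 and 2.24) and the endothelin receptor genes Ednrb (2.13 and 2.32) and Ednra (1.63 and 1.98) rose, and Chrm1, a muscarinic receptor of spiny neurons, fell (-0.89 and -1.04). Of 22 genes of the Gq, phospholipase C and calcium store list, 9 were higher and 10 lower with bARK(D110A) and 9 and 11 with bARK (medians -0.12 and -0.05, means -0.00 and 0.07; adjusted p = 0.897 and 0.882, with camera's direction up). Plcb3 (1.87 and 2.11) and the calcium release channel gene Itpr2 (1.28 and 1.61) rose, and Plcb2 fell (-2.18 and -1.86). Of 16 immediate early genes, 3 were higher in each construct and 6 and 7 lower (medians -0.21 and -0.32; adjusted p = 0.838 and 0.690), with Egr3 lower (-1.03 and -1.17) and Cyr61 (1.86 and 1.99) and Jun (0.98 and 1.19) higher. The counts adjusted over the list alone were the same for these 3 lists.

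Nuclear-retained noncoding RNAs and most RNAs of ribosomal protein genes were lower in IP. All 7 nuclear-retained noncoding RNAs fell, over all genes and adjusted over the list alone (medians -2.43 and -2.27; adjusted p = 2.99e-09 and 2.90e-07; with an estimated correlation, adjusted p = 0.0101 and 0.021), such as Meg3 (-2.90 and -2.60), Rian (-2.43 and -2.28) and Snhg11 (-2.77 and -2.36). Of 75 ribosomal protein genes, 0 were higher and 71 lower with bARK(D110A), and 1 and 69 with bARK; adjusted over the list alone, 72 and 71 were lower (medians -1.01 and -0.86). This list was called in both constructs (adjusted p = 6.77e-18 and 4.75e-12), and with an estimated correlation in bARK(D110A) alone (adjusted p = 0.0393, against adjusted p = 0.0934 with an estimated correlation in bARK). Rplp1 changed by -2.08 and -1.90 and Rps2 by -1.16 and -1.10. Of 73 oxidative phosphorylation subunits, 40 and 41 were higher and 12 in each construct lower, also adjusted over the list alone (medians 0.14 and 0.20; adjusted p = 0.0229 and 0.0144; adjusted p = 0.808 and 0.8291 with an estimated correlation), with Ndufc2 (0.72 and 0.87) and Uqcrc2 (0.76 and 0.79) among the higher. With library size as the only scaling this list was not called (adjusted p = 0.102 and 0.0564). In the test with mouse as a block and an estimated correlation, no list of this paragraph was called: adjusted p = 0.0512 and 0.0722 for noncoding RNAs, 0.107 and 0.183 for ribosomal protein genes and 0.588 and 0.592 for oxidative phosphorylation.

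**Figure D2:**
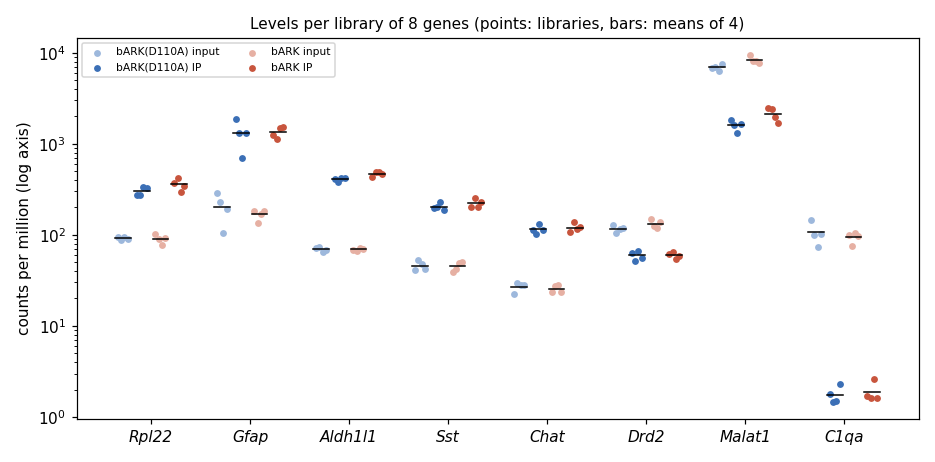
CPM (y axis, log scale) of Rpl22, Gfap, Aldh1l1, Sst, Chat, Drd2, Malat1 and C1qa in each of the 16 libraries, in 4 groups (x axis); points are libraries and bars are means of 4. Aldh1l1 rises from a mean of 69.4 CPM in bARK(D110A) input to 406 CPM in bARK(D110A) IP, and C1qa falls from 106 to 1.76 CPM.

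The study's main question was whether attenuating Gq signalling changed the RNA on astrocyte ribosomes. In IP, no single gene differed between bARK and bARK(D110A) past the threshold, and the shifts seen in groups of genes were small. The IPs also held neuronal and oligodendrocyte RNA, so a difference in IP need not come from astrocytes. The smallest p belonged to Alpk1, a kinase of innate immune sensing (chromosome 3, 127666718 to 127780547), at 6.19 ± 0.25 CPM (SD, n = 4) with bARK(D110A) and 9.07 ± 0.52 CPM with bARK, a log2 difference of 0.56 ± 0.07 that did not pass (adjusted p = 0.324). Trp53inp1, a p53-induced gene, was at 124 ± 2.46 and 148 ± 6.33 CPM (0.26 ± 0.04), the noncoding RNA Snhg11 at 71.6 ± 5.31 and 99.8 ± 10.02 CPM (0.48 ± 0.08) and Mcur1, a regulator of mitochondrial calcium uptake, at 49.4 ± 1.88 and 62.2 ± 3.86 CPM (0.34 ± 0.05), each with adjusted p = 0.324. The others among the 10 smallest, none of which passed, were the noncoding transcripts A330023F24Rik (0.64 ± 0.10) and 9530091C08Rik (0.77 ± 0.13), the cyclin gene Ccnd2 (0.27 ± 0.05), the p53-induced nuclease gene Aen (0.26 ± 0.05), the cohesin loader gene Nipbl (0.24 ± 0.04) and Vcl, the focal adhesion protein vinculin (0.29 ± 0.05). All 10 were higher with bARK. Adrbk1 differed by 0.15 ± 0.10 (adjusted p = 0.668) and Rpl22 by 0.25 ± 0.10 (adjusted p = 0.569).

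Of 15006 genes tested in IP, 0 passed with edgeR and 1287 had an unadjusted p under 0.05, 789 of them higher with bARK, where 750.3 would be expected by chance. This count depended on single libraries: it was 828 without library 2 of bARK(D110A) IP, 861 without library 2 of bARK IP and 1682 without library 1 of bARK(D110A) IP. limma-voom called 0 genes (1270 at an unadjusted p under 0.05), and DESeq2 called 45 (37 higher, 8 lower; 1288 at an unadjusted p under 0.05), including 9 of the 10 genes above, all but 9530091C08Rik. For 92.3% of the genes the 95% interval lay within a 2-fold change either way, and the 95th percentile of the absolute log2 difference was 0.38.

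With the preset correlation alone, astrocyte markers were higher and spiny and pan-neuronal markers lower with bARK in IP, without a member that passed over all genes. Astrocyte markers had a median log2 difference of 0.15 (adjusted p = 1.14e-09; adjusted p = 0.417 with an estimated correlation), with Aldh1l1 at 0.21 ± 0.06 and Fgfr3 at 0.23 ± 0.07. The transport genes were at 0.15 (adjusted p = 5.07e-05; adjusted p = 0.417 with an estimated correlation). Synapse-regulating genes were at 0.10 (adjusted p = 0.00603; adjusted p = 0.417 with an estimated correlation). Of these, Gpc6 passed adjusted over the list alone (0.25 ± 0.06). Cholesterol synthesis genes were at 0.19 (adjusted p = 1.13e-06; adjusted p = 0.434 with an estimated correlation), with Lss at 0.20 ± 0.08. Nuclear-retained noncoding RNAs were at 0.36 (adjusted p = 1.94e-09; adjusted p = 0.149 with an estimated correlation), and 3 of the 7, Snhg11, Meg3 (0.36 ± 0.09) and Malat1 (0.42 ± 0.14), passed adjusted over the list alone. Ribosomal protein genes were at 0.09 (adjusted p = 1.11e-05; adjusted p = 0.417 with an estimated correlation). These 6 lists were also called in each fit that left out 1 library. In the same libraries medium spiny neuron markers were at -0.11 (adjusted p = 0.000962; adjusted p = 0.511 with an estimated correlation) and pan-neuronal markers at -0.10 (adjusted p = 0.00123; adjusted p = 0.434 with an estimated correlation), with the GABA enzyme gene Gad2 at -0.18 ± 0.08. In these 8 lists 0 members passed over all genes, and 0 adjusted over the list alone apart from the 4 named.

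Other lists called in IP were the interferon genes (median 0.40, adjusted p = 0.00381; adjusted p = 0.567 with an estimated correlation), with Isg15 at 0.63 ± 0.42, and the immediate early genes (0.12, adjusted p = 0.0043; adjusted p = 0.417 with an estimated correlation), with Egr1 at 0.43 ± 0.15. So were oligodendrocyte precursor markers (0.22, adjusted p = 0.00887; adjusted p = 0.417 with an estimated correlation) and mural markers (0.20, adjusted p = 0.0209; adjusted p = 0.417 with an estimated correlation). Leaving out 1 library ended some calls. Without library 3 of bARK(D110A) IP the adjusted p was 0.352 for spiny neuron markers, 0.0713 for immediate early genes and 0.172 for interferon genes. Without its library 2 it was 0.0724 for pan-neuronal markers, 0.0895 for interferon genes and 0.0724 for mural markers. Without library 3 of bARK IP it was 0.168 for interferon genes, without library 2 of that group 0.137 for mural markers. For precursor markers it was 0.160 without library 1 of bARK(D110A) IP and 0.0722 without library 1 of bARK IP. Not called were interneuron (median 0.08, adjusted p = 0.0662), oligodendrocyte (-0.19, 0.0979), microglia (0.10, 0.177), endothelial (0.11, 0.540), and ependymal markers (-0.33, 0.256). Nor were pan-reactive (0.13, 0.0577), A1 (0.06, mean -0.01, 0.990) and A2 genes (-0.19, mean 0.02, 0.745), Gq-coupled receptors (-0.12, 0.176), the Gq pathway (0.03, 0.453) and oxidative phosphorylation (0.03, 0.0574). Among Gq genes, Ednra was at 0.30 ± 0.08, the glutamate receptor gene Grm5 at -0.25 ± 0.08 and Itpr2 at 0.25 ± 0.06, the last of which passed adjusted over the list alone. The fry test called 0 of the 23 lists.

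**Figure D3:**
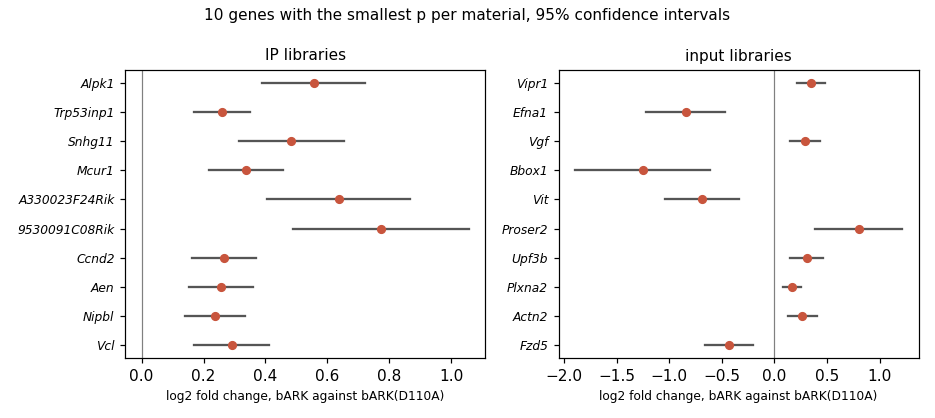
Log2 fold change of bARK against bARK(D110A) (x axis) with 95% intervals for the 10 genes (y axis) with the smallest p in IP (left) and in input (right), from 4 libraries against 4. None passed the adjusted threshold; Alpk1 in IP is at 0.56 and Vipr1 in input at 0.35.

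In input, which asks the same of the bulk striatum, again no gene passed. With the preset correlation alone, oligodendrocyte markers were lower and immediate early genes higher with bARK. The smallest p belonged to Vipr1, a receptor of vasoactive intestinal peptide, at 21.7 ± 1.40 CPM (SD, n = 4) with bARK(D110A) and 27.8 ± 1.56 CPM with bARK (0.35 ± 0.06, adjusted p = 0.774). The neuropeptide precursor gene Vgf was at 188 ± 9.67 and 232 ± 20.8 CPM (0.29 ± 0.06), and Efna1, a ligand of Eph receptors, at 3.01 ± 0.43 and 1.69 ± 0.23 CPM (-0.84 ± 0.17). The rest of the 10 were Bbox1, of carnitine synthesis (-1.25 ± 0.29), Vit (-0.69 ± 0.16), Proser2 (0.80 ± 0.19), the nonsense-mediated decay factor gene Upf3b (0.31 ± 0.07), the semaphorin receptor gene Plxna2 (0.16 ± 0.04), the actin crosslinker gene Actn2 (0.26 ± 0.06) and the Wnt receptor gene Fzd5 (-0.43 ± 0.10), each with adjusted p = 0.774. Of 15361 genes tested, 0 passed with edgeR and 904 had an unadjusted p under 0.05, 425 higher and 479 lower, where 768 would be expected by chance. This count was 484 without library 4 and 568 without library 1 of bARK input, and 1583 without library 3 of bARK(D110A) input. DESeq2 and limma-voom also called 0 (986 and 862 at an unadjusted p under 0.05). The interval lay within a 2-fold change for 92.7% of genes. Adrbk1 differed by -0.05 ± 0.08 (adjusted p = 0.897).

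Among the lists in input, oligodendrocyte markers had a median of -0.32 (adjusted p = 4.71e-10; adjusted p = 0.556 with an estimated correlation), with the myelin genes Cldn11 (-0.32 ± 0.13) and Cnp (-0.33 ± 0.14). Their mean log2 CPM in the 4 libraries was 7.75, 7.98, 7.24 and 7.58 with bARK(D110A) and 7.39, 7.45, 7.31 and 7.30 with bARK. Beside these shifts, immediate early genes were at 0.20 (adjusted p = 8.52e-06; adjusted p = 0.369 with an estimated correlation). Junb (0.30 ± 0.08), Egr3 (0.23 ± 0.06) and Arc (0.47 ± 0.12) passed adjusted over the list alone, and fry called this list for change in either direction (adjusted p = 0.0322). Spiny neuron markers were at 0.09 (adjusted p = 1.45e-05; adjusted p = 0.597 with an estimated correlation), with the enkephalin gene Penk at 0.15 ± 0.05 and the dopamine receptor gene Drd2 at 0.18 ± 0.08. Lower lists were precursor markers (-0.13, adjusted p = 0.000676; adjusted p = 0.556 with an estimated correlation) and astrocyte markers (-0.08, adjusted p = 0.00526; adjusted p = 0.676 with an estimated correlation). So were ependymal markers (-0.51, adjusted p = 0.00526; adjusted p = 0.556 with an estimated correlation), with Foxj1 at -0.38 ± 0.18, ribosomal protein genes (-0.06, adjusted p = 0.00573; adjusted p = 0.676 with an estimated correlation) and microglia markers (-0.13, adjusted p = 0.00724; adjusted p = 0.676 with an estimated correlation). Without library 2 of bARK(D110A) input the adjusted p was 0.413 for astrocyte and 0.0923 for spiny neuron markers. Without its library 1 it was 0.0993 for ependymal and 0.624 for microglia markers and 0.256 for ribosomal protein genes. Without library 4 of bARK input it was 0.0909 for ribosomal protein genes, and without library 2 of that group 0.0781 for microglia markers. In no list did a member pass over all genes, and none passed adjusted over the list alone apart from the 3 named.

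Lists without a call in input were pan-neuronal (median 0.03, adjusted p = 0.151), interneuron (-0.02, 0.577), endothelial (-0.04, 0.194) and mural markers (-0.03, 0.577). The same held for pan-reactive (-0.06, 0.921), A1 (-0.18, 0.872) and A2 genes (-0.22, 0.143), Gq-coupled receptors (-0.02, 0.948), the Gq pathway (0.01, mean -0.05, 0.206) and interferon genes (0.13, 0.194). Neither were cholesterol synthesis (-0.01, 0.577), transport (-0.07, 0.143), synapse-regulating genes (-0.10, 0.375), noncoding RNAs (0.07, 0.076) and oxidative phosphorylation called (-0.00, 0.905). By direction, fry called 0 lists in input.

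The last comparison asked whether the enrichment itself differed between constructs. No gene passed. With the preset correlation alone, astrocyte markers were enriched slightly more and spiny neuron markers depleted slightly more with bARK. Limd1, an adaptor of the Hippo pathway, had the smallest p, with an enrichment of 0.66 ± 0.06 with bARK(D110A) and 1.05 ± 0.06 with bARK, a difference of 0.40 ± 0.08 (adjusted p = 0.825). Close to it stood Pacsin3 (0.41 ± 0.10), Popdc3 (0.97 ± 0.23), Ppp1r14b (0.44 ± 0.11), Rapgef3, a cAMP-activated exchange factor (0.38 ± 0.09), and the noncoding RNA Firre (0.50 ± 0.12). Others were the urate transporter gene Slc2a9 (0.86 ± 0.21), the olfactory receptor gene Olfr690 (-2.74 ± 0.68) and Fkbp10 (0.50 ± 0.13), and none of these 8 passed (adjusted p = 0.825 each). Of 15850 genes, 0 passed with edgeR, and 951 had an unadjusted p under 0.05, 646 positive and 305 negative, where 792.5 would be expected by chance. This count was 612 without library 2 of bARK IP and 1529 without library 1 of bARK(D110A) IP. Without both libraries of mouse 2 it was 482 for bARK(D110A) and 584 for bARK, in fits chosen after seeing the data. DESeq2 and limma-voom called 0 (1004 and 863 at an unadjusted p under 0.05), and mouse as a block also gave 0, with 1851 at an unadjusted p under 0.05 and a smallest adjusted p of 0.339. The interval lay within a 2-fold change for 82.4% of genes.

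Of the lists, astrocyte markers differed by a median of 0.23 (adjusted p = 5.28e-12), transport genes by 0.20 (1.11e-05), synapse-regulating genes by 0.23 (0.00277), oligodendrocyte precursor markers by 0.34 (3.07e-05), noncoding RNAs by 0.20 (0.00385) and ribosomal protein genes by 0.16 (3.63e-09), each with adjusted p = 0.313 with an estimated correlation. Cholesterol synthesis genes differed by 0.20 (adjusted p = 0.000267; adjusted p = 0.505 with an estimated correlation), spiny neuron markers by -0.17 (adjusted p = 9.27e-08; adjusted p = 0.345 with an estimated correlation) and pan-neuronal markers by -0.12 (adjusted p = 0.000223; adjusted p = 0.368 with an estimated correlation). Microglia markers differed by 0.27 (adjusted p = 0.00277; adjusted p = 0.496 with an estimated correlation) and mural markers by 0.18 (adjusted p = 0.0281; adjusted p = 0.368 with an estimated correlation). Examples were Aldh1l1 (0.23 ± 0.08), Fgfr3 (0.28 ± 0.10), Rbfox3 (-0.22 ± 0.08), Gnal, the G protein of spiny neurons (-0.24 ± 0.11), and Rps9 (0.31 ± 0.08). Over all genes 0 members passed. Adjusted over the list alone, Gpr17 (0.42 ± 0.12) and Susd5 (0.64 ± 0.23) of the precursor markers passed, as did Rgs5 (0.42 ± 0.11) of the mural markers. With mouse as a block the mural list was not called (adjusted p = 0.0775), and the pan-reactive list (adjusted p = 0.0046; 0.372 with an estimated correlation) and the interferon list (adjusted p = 0.000791; 0.464 with an estimated correlation) were. The mural call was also lost without library 1 or 4 of bARK(D110A) input, library 3 of bARK input, or library 2 or 4 of bARK IP (adjusted p = 0.0641, 0.0934, 0.105, 0.108 and 0.0615). The microglia call was lost without library 1 of bARK(D110A) input, library 3 of bARK(D110A) IP or library 3 of bARK IP (adjusted p = 0.0641, 0.0502 and 0.107).

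The other lists were not called: interneuron (median 0.16, adjusted p = 0.118), oligodendrocyte (0.10, 0.418), endothelial (0.16, 0.1698) and ependymal markers (0.32, 0.665). Nor were pan-reactive (0.26, 0.1698), A1 (0.22, 0.999) and A2 genes (0.21, 0.578), Gq-coupled receptors (-0.12, mean 0.05, 0.547), the Gq pathway (0.01, mean 0.07, camera's direction down, 0.716), immediate early genes (-0.05, 0.475), interferon genes (0.24, 0.461) and oxidative phosphorylation (0.04, 0.122). The fry test called 0 lists.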

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

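The counts of genes at an unadjusted p under 0.05, of lists called and of genes called by DESeq2 in other splits of the libraries, and the tests of purer precipitates and of less carry-over, were chosen only after the results they test had been seen, while the splits for genes called and the split counts with mouse as a block were chosen before.

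In 11 of 264 groups of 4 libraries, 1 library lay far from the other 3; chance gives about 13.2 such groups. In input these were library 1 of bARK(D110A) for Cox6b2 (3.03 CPM against 2.54 to 2.58), library 2 of bARK(D110A) for Rapgef3 (26.4 against 23.1 to 23.7) and library 3 of bARK for Itgam (44.8 against 38.7 to 39.6). In bARK(D110A) IP, library 2 was low for Snhg11 (63.7 against 74.1 to 74.4 CPM) and Limd1 (29.3 against 33.0 to 33.6). In bARK IP, library 2 was high for Acsbg1 (1112 against 945 to 956 CPM), Pacsin3 (75.4 against 65.2 to 66.6) and the mean log2 CPM of astrocyte markers (9.10 against 8.88 to 8.91). Library 3 of that group was high for the microglia genes Ctss (4.98 against 2.01 to 2.49 CPM), C1qa (2.59 against 1.61 to 1.71) and Csf1r (5.03 against 3.23 to 3.50).

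The enrichment differed between constructs in 11 of 23 lists by camera's test of the interaction with the preset correlation. The adjusted p was 5.28e-12 for astrocyte markers, 0.000223 for pan-neuronal markers, 9.27e-08 for spiny neuron markers, 3.07e-05 for oligodendrocyte precursor markers, 0.00277 for microglia markers, 0.0281 for mural markers, 0.000267 for cholesterol synthesis genes, 1.11e-05 for transport genes, 0.00277 for synapse-regulating genes, 0.00385 for nuclear-retained noncoding RNAs and 3.63e-09 for ribosomal protein genes. With an estimated correlation 0 of these calls held, the smallest adjusted p being 0.313.

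The first pattern weighed is the enrichment of RNA by the precipitation. Of the 35 splits of the 8 libraries of bARK(D110A), only the real one gave as many genes (1 split, 11677 genes, highest other 28), and the same was true for bARK (1 split, 12010 genes, highest other 0). Among the 8 splits that part all 4 pairs of a construct, the real one again stood alone, with 0 genes as the highest other count. No other grouping of the libraries came near these counts. Each other split mixes IP and input libraries within a group, which widens the spread, so its count is bound to be low where enrichment is strong.

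The second pattern is the small difference between constructs, where no gene was called, so all 35 splits of the libraries gave as many genes in IP, 35 in input and 35 for the difference of enrichment, with 1, 4 and 0 genes as the highest other count, which tests nothing. Of the genes at an unadjusted p under 0.05, 4 of 35 splits gave as many as the real 1287 in IP (highest other 1629), 11 of 35 as many as 904 in input (highest other 1415) and 1 of 35 as many as 951 for the difference of enrichment (highest other 805), or 1 of 35 as many as 1851 with mouse as a block (highest other 1558). Chance remains an explanation for IP and input, and for the difference of enrichment 1 of 35 is the smallest share this test can give. For the 45 genes of DESeq2 in IP, 8 of 35 splits gave as many. In 1 of them DESeq2 called 357, several times the real count, where edgeR called 0. That split put libraries 1 and 2 of bARK(D110A) IP with libraries 1 and 4 of bARK IP. Among the IPs these were also the highest on the third principal component (-1.51, 27.6, 6.38 and 11.5, the next being -7.32). A structure of the samples across constructs thus goes with this count, and the part of the test used was not told apart here. Lists called in IP, in input and for the difference reached the real 12, 8 and 11 in 8, 22 and 3 of 35 splits, with 16, 14 and 12 as the highest other counts. The median of the other splits was 9, 9 and 6 lists. With the preset correlation, lists were thus called in arbitrary groupings too, and its small p-values do not show a difference between constructs.

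The third pattern is that astrocyte lists were higher and spiny and pan-neuronal lists lower with bARK in IP, calls that were lost with an estimated correlation (adjusted p = 0.417, 0.511 and 0.434 for astrocyte, spiny neuron and pan-neuronal markers). As 8 of 35 splits gave as many called lists (12, highest other 16), chance remains open, and so do purer precipitates, which would lower the markers of every other cell type, whereas 2 of 4 such lists had a median above 0. In mean log2 CPM the endothelial (median 0.11) and microglia lists (0.10) differed by 0.0682 ± 0.0644 (SE, n = 4 against 4) and 0.115 ± 0.151, the pan-neuronal (-0.10) and spiny neuron lists (-0.11) by -0.0921 ± 0.142 and -0.0981 ± 0.0838, and the precursor (0.22) and mural lists (0.20), not among the 4, by 0.143 ± 0.0965 and 0.0949 ± 0.102. None of these passed 2 standard errors, a bound widened from 1, which the endothelial list passed, and moved from the median to this difference, both after the values had been seen. The precursor and mural lists were added because they had been called higher in IP with bARK. Oligodendrocyte (-0.19) and ependymal markers, also outside the 4, had medians below 0, and interneuron markers had a median above 0. Less carry-over of input RNA would also lower nuclear-retained RNAs, yet their median was 0.36 (difference 0.309 ± 0.0751, adjusted p = 0.149 with an estimated correlation). This argues against it for these RNAs only. The list had already been seen to be higher and no split was run on it alone, so a chance difference is not excluded. An effect of attenuated Gq signalling on astrocyte RNA is open as well.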

How the results depend on the processing

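The fits that left out both libraries of a mouse, and the block with an estimated correlation, were chosen only after the data had been seen, while the other alternatives were planned. For enrichment, 46 list results were followed through 769 alternatives: 712 kept direction and side of the threshold, 28 no longer passed, 22 newly passed and 7 turned direction. The 217 results of named genes had 4557 alternatives, of which 4480 kept both, 57 no longer passed, 19 newly passed and 1 turned. For the construct comparisons and the difference of enrichment, 69 list results had 1220 alternatives, of which 944 kept both, 124 no longer passed, 61 newly passed, 71 turned and 20 moved in size only. The 175 gene results had 3708 alternatives, of which 3692 kept both, 9 newly passed and 7 turned. A list that was not called was followed by the sign of its median, a rule that replaced an earlier one after results had been seen and on which these counts depend. Enrichment called 10738 to 12400 genes with bARK(D110A) and 11016 to 12659 with bARK under the other scalings, filters, tests and sets of libraries, and 10870 to 11661 and 11259 to 11801 in the fits that left libraries out. Adding a 2-fold limit left 3963 genes with bARK(D110A) (1835 higher, 2128 lower) and 4374 with bARK (2155 higher, 2219 lower), which follows from the stricter limit. In IP between constructs DESeq2 called 45 genes against 0 in edgeR; the cause was not tested. At this depth and spread, 1.5-fold changes between constructs in IP were recovered in 66.5% of simulated genes. Each draw held 200 changed genes, drawn independently, so this share does not carry over to a comparison with few changed genes.

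For enrichment, the reported test called 11 of the 23 lists in each construct. Of the 23, camera with an estimated correlation called 7 with bARK(D110A) and 6 with bARK, and fry, which also called lists that the reported test did not, called 17 and 18. For the construct comparison in IP (12 lists called), in input (8) and for the difference of enrichment (11), the estimated correlation called 0, 0 and 0 and fry by direction 0, 0 and 0, while fry for change in either direction called the immediate early genes in input (adjusted p = 0.0322). The replicate block with an estimated correlation called 3 and 2 lists for enrichment and 0 in each of the other 3 comparisons, and the astrocyte list then had adjusted p = 0.0512 and 0.0673 for enrichment. An estimated correlation above the preset one widens the error of a list, and no further cause was tested. Beyond the list calls given with the results, the mouse block changed no other call of a list, and it called 12400 and 12659 genes for enrichment and 0 for the difference. Across constructs the numbers name different mice: the correlation of deviations was -0.256 to -0.0867 in IP, over 0.1 in 0 of 4 pairs, and -0.0652 to 0.103 in input, over 0.1 in 1 of 4. The block by number left the count of genes at 0 in IP and 0 in input, with 976 and 1133 at an unadjusted p under 0.05, and added a call of the pan-reactive list in IP (adjusted p = 0.0219).

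Some medians and fold changes, none past a threshold in the reported test, turned direction, and the cause was not tested. With library size only, Adrbk1 in enrichment with bARK(D110A) was at -0.0427, the pan-neuronal median with bARK at -0.0767 and the Gq pathway median in input at -0.0154. With DESeq2 size factors the oxidative phosphorylation median in input was 0.00380. The rest turned when libraries were left out, and are given as the lowest and highest values over those fits. For enrichment with bARK(D110A) these were -0.0712 and 0.39 for oligodendrocyte markers and -0.14 and 0.0315 for the Gq pathway, and with bARK -0.0669 and 0.11 for pan-neuronal markers. Between constructs in IP they were -0.40 and 0.0464 for oligodendrocyte markers, -0.0233 and 0.34 for pan-reactive, -0.24 and 0.26 for A1 and -0.35 and 0.12 for A2 genes. In input the list medians were -0.0103 and 0.11 (pan-neuronal), -0.10 and 0.0626 (interneuron), -0.0810 and 0.00481 (mural), -0.15 and 0.12 (pan-reactive), -0.43 and 0.21 (A1), -0.0870 and 0.0304 (Gq-coupled receptors), -0.00965 and 0.0386 (Gq pathway) and -0.0936 and 0.39 (interferon). They were also -0.0476 and 0.0573 (cholesterol synthesis), -0.0835 and 0.00321 (transport), -0.00823 and 0.15 (noncoding RNAs) and -0.0143 and 0.0102 (oxidative phosphorylation). Single genes in input were at -0.0801 and 0.0470 (Rpl22), -0.0870 and 0.0249 (Adrbk1), -0.65 and 0.16 (Pvalb), -0.50 and 0.13 (B2m) and -0.00823 and 0.13 (Rian). For the difference of enrichment they were -0.10 and 0.35 (oligodendrocyte), -0.10 and 0.62 (ependymal), -0.22 and 0.58 (A1), -0.12 and 0.45 (A2), -0.20 and 0.0738 (Gq-coupled receptors), -0.0482 and 0.00772 (Gq pathway), -0.18 and 0.00204 (immediate early genes), -0.0376 and 0.49 (interferon) and -0.16 and 1.02 (Alas2). Other medians moved by more than the SD of their list's members without turning and without a new call of the list, all in fits without libraries. They were oligodendrocyte in IP (-0.19 to -0.0938) and A1 in input (-0.18 to -0.430 and -0.380). For the difference they were interneuron (0.16 to 0.0295), A1 (0.22 to 0.579), oligodendrocyte (0.10 to between 0.0221 and 0.0412) and interferon (0.24 to between 0.0420 and 0.424). Fits that newly called a list are not in these ranges, and some moved further. The oligodendrocyte median reached -0.40 in IP and 0.35 for the difference, and the interferon median 0.49 for the difference. Over the same fits the count of lists called was 11 to 12 and 11 for enrichment, 9 to 15 in IP, 7 to 12 in input and 10 to 14 for the difference of enrichment.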

Other observations

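The test of carry-over was chosen only after the enrichment of interneuron markers had been seen. The tests on further interneuron genes and on p53 target genes were chosen before the values of those genes were looked up, on lists written after the first genes of each pattern had been seen.

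Mice differed from each other in interferon genes by more than the constructs did. The mean log2 CPM of the 12 genes was 5.57, 4.03, 4.27 and 5.39 in the 4 bARK(D110A) inputs and 6.999, 5.81, 5.71 and 6.82 in the IPs of the same mice. It was 4.88, 4.60, 5.34 and 5.35 in the bARK inputs and 6.32, 6.49, 7.31 and 6.91 in their IPs. Oligodendrocyte markers in the bARK(D110A) IPs were at 8.36, 7.92, 6.85 and 7.60, and at 7.75, 7.98, 7.24 and 7.58 in the inputs of the same mice. In both lists library 3 of bARK(D110A) was the lowest of its IP group. Gfap had 1882, 1303, 706 and 1308 CPM in the bARK(D110A) IPs and 1238, 1122, 1494 and 1545 CPM in the bARK IPs.

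In IP, 6 of 8 interneuron markers were higher in both constructs (lowest of the 8, -0.71 and -0.27) although 18 of 18 markers of the far more numerous spiny neurons were lower. With an estimated correlation neither list was called (adjusted p = 0.0585 and 0.0808 for interneuron, 0.277 and 0.211 for spiny neuron markers). Carry-over of RNA from neurons in general would bring both. The interneuron median (2.05 and 2.19) lay at least 2.70 above the highest spiny neuron marker (-0.65 with bARK(D110A), -0.86 with bARK), which argues against such shared carry-over. This gap restates the pattern that raised the question, so it is no separate test. A candidate explanation is tagged ribosomes in cholinergic and somatostatin interneurons: of 10 further genes of these cells, 8 were higher in IP in both constructs, with medians of 1.58 and 1.84, among them Lhx8 (1.42 ± 0.10 and 1.53 ± 0.10) and Chodl (2.08 ± 0.17 and 2.16 ± 0.17). Rbp4 was lower (-0.98 and -1.26) and Isl1 did not pass (-0.11 and -0.19). This remains a hypothesis, since the tag itself was not measured by cell type here.

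Trp53inp1 and Aen, 2 of the 10 genes with the smallest p between constructs in IP, are induced by p53. In 18 further p53 target genes, the median log2 difference in IP was 0.15, with 15 of 18 above 0. This was at percentile 100 of 10000 random lists matched on expression and at 99.94 of 10000 matched on IP enrichment. The random lists were drawn gene by gene and keep no shared movement of target genes, so the percentiles cannot decide. Purer astrocyte precipitates therefore stay open. Of the 18 genes, 13 were themselves higher and 1 lower in IP than in input in each construct. Their median enrichment was 0.62 with bARK(D110A) and 0.78 with bARK. Chance stays open: 1 of 35 splits, the real one, gave a median as large, but p53 was picked from the top genes of that split, 1 of 35 is the smallest share possible, and the highest other (0.135) lay within the 0.13 to 0.18 seen when each library was left out. Higher p53 target genes in the IPs with bARK may be a candidate explanation, but 0 of the 18 passed over all genes. Adjusted over the list alone, 4 did: Sesn2 (0.22 ± 0.05), Bax (0.20 ± 0.05), Cdkn1a (0.39 ± 0.10) and Ccng1 (0.22 ± 0.06). In input the median was -0.03, with 8 of 18 above 0.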
